A study of Onthophagus taurus with 15 samples.

How the data were processed

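Gene expression was measured on spotted two-colour arrays in large male pupae of the horned dung beetle Onthophagus taurus, taken within 24 h of pupation. Each of the 15 arrays carried RNA of 1 appendage tissue in one dye and RNA of dorsal abdominal epithelium in the other. The tissues were head horn, thoracic horn and legs, with 5 arrays each, lettered A to E. Per the labels, each RNA sample pooled tissue of 4 pupae, both samples of an array came from the same animals, and the RNA was amplified by in vitro transcription before labelling with Cy3 or Cy5. In each tissue the appendage was in Cy3 on 3 arrays (A, C and E) and in Cy5 on 2 arrays (B and D).

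The deposited table held 1 value per clone and array for 3840 clones, 1920 with the prefix OtL and 1920 with the prefix OtP. These deposited values were read as log2 ratios of both channels, which the authors had already normalized, with limma according to the submitters' processing notes. The background correction, the normalization method, the filter behind the 1799 empty cells and the log base are not given in the sources used here. The log2 scale was taken because limma works on it. Scanner intensities were not used here, so the signal behind each ratio is unknown. The number of arrays limits the precision.

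The sign of the deposited values was examined by a preset rule. Within each tissue, arrays of opposite dye layout correlated above 0 over all clones, at 0.25 to 0.50, and arrays of the same layout at 0.60 to 0.72. By this rule the values were taken as already turned for the dye flips, and no array was turned again. Dye bias of single clones could also raise such correlations, so they do not settle the point alone. Unturned values would place differences between tissues in the layout term rather than in the ratios. With a layout term per tissue, ratios differed in 98 clones (head horn and legs), 189 (thoracic horn and legs) and 16 (the horns). The layout term differed in 1, 0 and 0, which argues against unturned values. Whether a positive value means appendage over abdomen is not stated. That direction is likely, since the sample titles and the series design name the appendage first and the appendage is always the first channel. If it were the other way round, every sign below would be turned, counts of positive and negative calls would change places, and no total of calls, absolute size or adjusted p would change. No sex, stage or marker gene was used to choose it.

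Neither the deposited table nor the gene table supplied with it (16956 genes) pairs clone IDs with genes. None of the clone IDs (0 of 3840) matched an entry of that gene table, so clones are reported by ID and by group. Gene lists that had been prepared in advance, and the set tests planned for them, could not be applied for the same reason. Several clones can come from 1 transcript, so counts of clones are not counts of genes.

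Clones with values on at least 3 arrays of each tissue and on both dye layouts were tested, which left 3777 clones and removed 63. Of the 3840 clones, 3182 had a value on all 15 arrays. One linear model per clone was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a coefficient for each tissue and 1 term for the dye layout, shared by the tissues. The layout term was included because 3 arrays against 2 leave part of any dye bias in a plain mean. The test of a tissue coefficient against 0 is the comparison of that tissue with abdominal epithelium of the same animals. The 3 differences between coefficients compare the tissues with each other, indirectly through abdomen. P-values were adjusted by the Benjamini-Hochberg method within each of the 6 comparisons. A clone is said to be called when its adjusted p is under 0.05. The p-values measure the spread between arrays, taken over the 3 tissues together. That spread joins differences between the pools of pupae with those of amplification, labelling and measurement. Figures were drawn with matplotlib 3.10.9.

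Letters A to E recur in the 3 tissues. Deviations of same-letter arrays from the tissue means correlated at 0.36 to 0.65 in all 15 pairs, and at 0.24 to 0.43 when deviations were taken within tissue and dye layout. Between tissues, arrays of other letters with the same layout reached 0.45 on the first measure and -0.04 on the second. Only on the second measure do same-letter and other-letter values part. The pairs of this measure are not independent, since deviations of B and D from their joint mean mirror each other. Deviations also cancel out over the letters of a layout, so positive same-letter values make the others negative. The -0.04 is therefore no separate reference, and the evidence lies in the same-letter values alone. The values thus pair same-letter arrays, on evidence from the data only, since the labels tie animals together within an array and not across arrays. The letter nevertheless stayed out of the model, a choice made before the data were examined, so calls and p-values given without mention of a block are from an unpaired fit. The correlations were computed after the calls with and without a letter block had been seen. Counts with it as a random or fixed block are given beside the comparisons between tissues. The letter and the dye layout cannot be separated, because each letter has the same layout in every tissue.

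The fit was tested on simulated data with the observed spreads, empty cells, layout effects and a correlation within letters. In a single run per comparison with normal errors, 67, 67 and 66 of 3777 clones were changed by 0.5, 1 and 2. The other clones had no difference in the comparison. In the data 1401 clones were called for head horn versus abdomen and 244 for head horn versus legs. The shares below depend on that proportion, so they describe the simulated setting only. For head horn versus abdomen, 58.2% of clones changed by 0.5 on the log2 scale, 70.1% of those changed by 1 and 92.4% of those changed by 2 were recovered, and 6.96% of calls were false. For head horn versus legs the recovered shares were 20.9%, 44.8% and 81.8% for the same changes, and 2% of calls were false. With the letter as a random block they were 35.8%, 65.7% and 90.9%, and 1.54% of calls were false. For head horn versus abdomen that block recovered 53.7%, 68.7% and 97.0%, and 7.59% of calls were false. Both false shares of head horn versus abdomen, 6.96% and 7.59%, lay above the adjusted p threshold of 0.05 in these single runs.

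The clones named were chosen by a rule written in advance for unnamed clones. They are the 2 highest and 2 lowest fitted values of each comparison among called clones with the same sign on every array of the tissue, or, between tissues, in at least 4 of the 5 letters. Clones chosen after their values were seen are marked. Alternatives covered the layout term, the filter on clones, centring and scaling of arrays, array weights, robust empirical Bayes, a fold threshold, separate fits, the letter block and leaving out each letter. After the data were seen, fits within each dye layout and a layout term per tissue were added.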

Results

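Expression in 3 appendages of large male Onthophagus taurus pupae was set against dorsal abdominal epithelium of the same animals, with 5 arrays for head horn, 5 for thoracic horn and 5 for legs. Head and thoracic horns are outgrowths of the body wall, and legs are jointed limbs. Between 3511 and 3808 of the 3840 clones had a value on an array, and the array medians lay between -0.07 and 0.15 on the log2 scale. Replicate D was the least complete in every tissue, with 295 to 329 clones empty, against 32 to 120 on the other arrays. Values are ratios taken as log2, since the base is not stated, and a positive value is likely to mean higher in the appendage, a direction the files do not settle. The clones carry no gene names here.

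The first comparison asked which clones differed between head horn and abdominal epithelium. Of 3777 clones tested, 1401 were called (limma, adjusted p under 0.05), 688 with positive and 713 with negative ratios. Among them, 462 differed at least 2-fold, 194 positive and 268 negative, and 165 differed at least 4-fold. OtP020-E08 had the highest ratio, at 3.91 ± 0.16 (fit ± SE, 15.1-fold, adjusted p = 5.96e-09 by limma), with a mean over arrays of 3.88 ± 0.46 (SD, n = 5). OtL014-H05 was nearly as high at 3.91 ± 0.63 (SE), with a wider spread between arrays of 1.46 (SD, n = 5). Its fit was 2.90 on letters A, C and E and 4.84 on letters B and D. The lowest ratio belonged to OtL011-A04, at -4.19 ± 0.26 (SE, 18.2-fold, adjusted p = 7.89e-08 by limma). It was followed by OtL006-A08 at -3.62 ± 0.33 (SE). The same sign on every array was a condition for naming these 4 clones, and 1096 of the 1401 called clones met it. Fitted within a dye layout, 889 clones were called on letters A, C and E and 797 on letters B and D. Such fits hold no layout term, so dye bias of a clone can enter these counts.

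Thoracic horn was compared with abdominal epithelium in the same way. Here 1291 clones were called, 637 positive and 654 negative, of which 367 differed at least 2-fold and 108 at least 4-fold. The highest ratio was that of OtP008-D05, at 4.46 ± 0.47 (SE, 22-fold, adjusted p = 4.66e-05 by limma), where replicate D alone stood at 6.14 and the other arrays between 3.46 and 3.98. The fit for this clone was 3.68 without letter D and 5.20 without letter B. OtL002-E05 had a ratio of 3.98 ± 0.18 (SE, 15.8-fold) in thoracic horn, 3.52 ± 0.18 in head horn and 1.03 ± 0.18 in legs. The lowest ratio was that of OtP001-H03, at -4.22 ± 0.39 (SE, 18.6-fold, adjusted p = 4.98e-06 by limma). OtL011-A04, the lowest clone of head horn, came next at -3.94 ± 0.26 (SE). The same sign was seen on every array for 1106 of the called clones. Within letters A, C and E 709 clones were called, and within B and D 500 clones, again with no layout term.

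The comparison of legs with abdominal epithelium gave 1506 called clones, 841 positive and 665 negative. Positive ratios made up 55.8% of these calls, and 49.6% once every array was centred on its median. At least 2-fold differences were seen in 455 clones, 172 positive and 283 negative, and at least 4-fold differences in 43 positive and 117 negative clones. OtL006-D08 was highest at 4.24 ± 0.21 (SE, 18.8-fold, adjusted p = 1.12e-08 by limma), followed by OtL009-F10 at 4.18 ± 0.32 (SE). Both were also called positive in the horns, OtL006-D08 at 3.46 ± 0.21 in head horn and 3.27 ± 0.21 in thoracic horn, and OtL009-F10 at 3.67 ± 0.32 and 3.39 ± 0.32. OtL011-A04 was again lowest, at -4.90 ± 0.26 (SE, 29.8-fold, adjusted p = 1.60e-08 by limma), with OtL004-F05 next at -4.64 ± 0.39 (SE). Within letters A, C and E 994 clones were called, and within B and D 741 clones, again with no layout term.

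A large part of the difference from abdomen was common to the appendages. Of the 2187 clones called in at least 1 tissue, 711 (32.5%) were called with the same sign in all 3, 322 positive and 389 negative. In 242 of these the difference was at least 2-fold in every tissue, 86 positive and 156 negative. Head and thoracic horn shared 454 positive and 521 negative clones, where independent lists of the same sizes would share 116 and 123. Head horn and legs shared 425 positive and 492 negative clones, against 153 and 126 for independent lists. Thoracic horn and legs shared 376 and 416 clones, against 142 and 115. By Fisher's exact test over clones, the odds ratios of these 6 overlaps ran from 8.28 to 59.7, with a largest two-sided p of 9.95e-113. Clones are not independent replicates, so that p describes the lists only. Abdomen is the reference in all 3 lists, so the lists need not be independent. What is common to the appendages cannot be told apart here from what is particular to abdominal epithelium.

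Abdominal samples of 1 letter may come from the same animals, so part of such agreement can arise from shared chance. The fitted ratios of head and thoracic horn correlated at 0.83 over clones, those of head horn and legs at 0.74 and those of thoracic horn and legs at 0.68. With the fitted effects removed and the signs of whole letters turned in 15 ways, the simulated means were 0.09, 0.13 and 0.13. The covariances were 0.51, 0.53 and 0.43, against simulated means of 0.012, 0.016 and 0.015. When the 2 tissues of a pair were taken from different letters, the covariances averaged 0.52, 0.53 and 0.43.

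**Figure D1:**
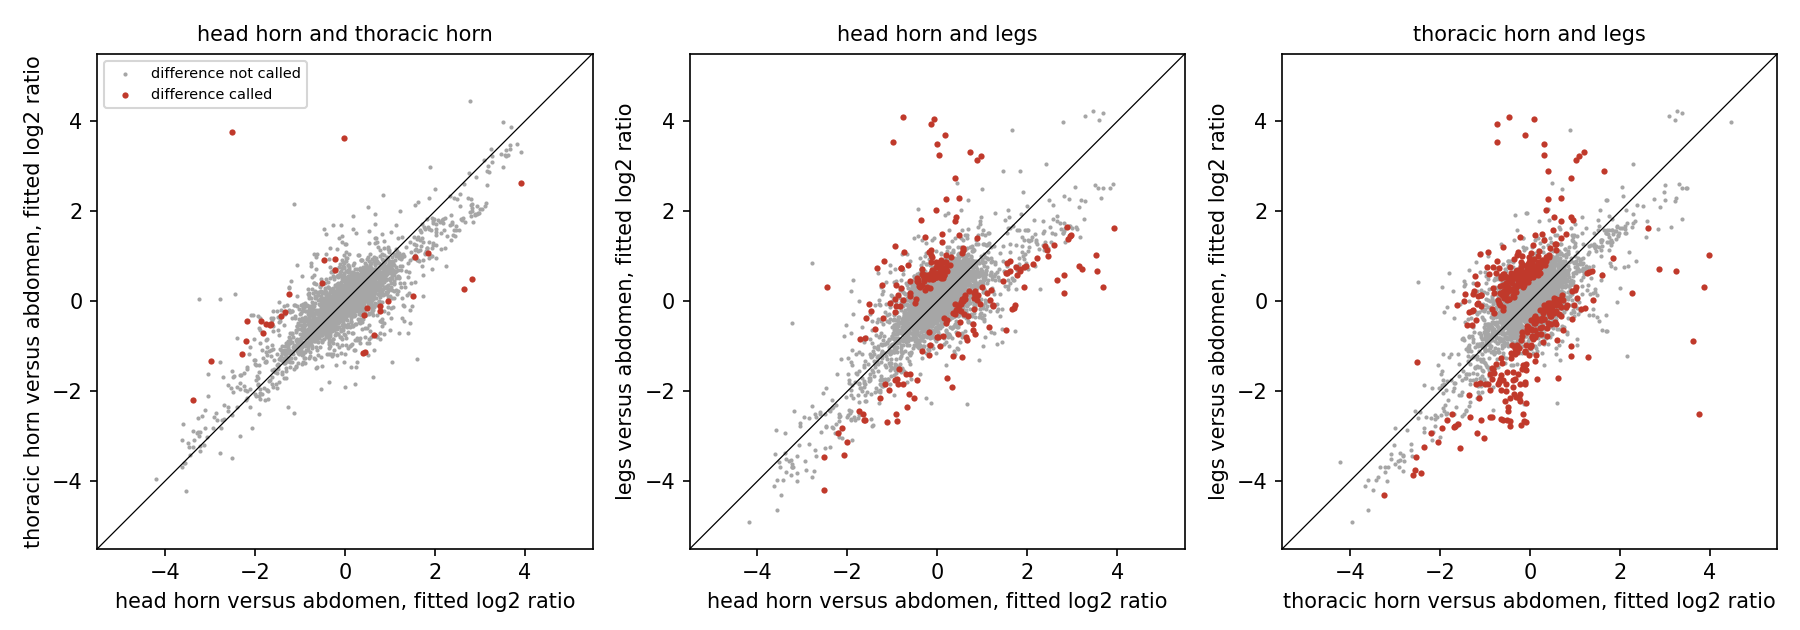
Fitted log2 ratios to abdomen of 3777 clones, one tissue on each axis, with the line of equal ratios; red points are clones whose difference between the 2 tissues was called. Points lie close to the line for the horns, with 33 differences called, and spread more widely for each horn against legs, with 244 and 415 called.

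The tissues were then compared with each other, which bears on how alike the horns and the legs are. Head horn and legs differed in 244 clones, 117 with the higher ratio in head horn and 127 with the higher ratio in legs. With arrays centred on their medians the split turned to 143 against 102. The largest differences in favour of head horn were those of OtP011-E02, by 3.36 ± 0.41 (SE, 10.3-fold, adjusted p = 5.19e-04 by limma), and OtP015-A03, by 2.89 ± 0.21 (SE, 7.42-fold, adjusted p = 8.36e-06). OtP011-E02 stood at 3.68 ± 0.29 in head horn, 3.86 ± 0.29 in thoracic horn and 0.32 ± 0.29 in legs. OtP015-A03 stood at 3.56, 3.25 and 0.67, each ± 0.15 (SE). In the other direction, OtP013-D04 differed by -4.87 ± 0.69 (SE, 29.2-fold, adjusted p = 0.00158 by limma) and OtP014-A08 by -4.12 ± 0.84 (SE, adjusted p = 0.0163). Both were near 4 in legs, at 4.09 ± 0.49 and 4.05 ± 0.60. In head horn neither was called against abdomen, with OtP013-D04 at -0.77 ± 0.49 and OtP014-A08 at -0.07 ± 0.60, and the arrays of OtP014-A08 spread by 2.48 (SD, n = 5). The difference of OtP014-A08 was no longer called without letter A, C or E (adjusted p = 0.0588, 0.0619 and 0.0624 by limma), and its size ranged from -3.45 without C to -4.93 without B.

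Thoracic horn and legs differed in 415 clones, 201 with the higher ratio in thoracic horn and 214 with the higher ratio in legs, and with centred arrays the split turned to 230 against 185. OtL014-H10 differed most, by 6.28 ± 0.70 (SE, 77.7-fold, adjusted p = 1.92e-04 by limma), followed by OtP012-E12, by 4.50 ± 0.49 (SE, 22.6-fold, adjusted p = 1.46e-04). Without letter C the difference of OtL014-H10 was 5.52. On the side of legs, OtP013-D01 differed by -4.65 ± 0.82 (SE, adjusted p = 0.00418 by limma) and OtP013-D04 by -4.55 ± 0.69 (SE, adjusted p = 0.00153). Both horns lay above legs in 71 clones and below legs in 86 clones, where independent lists would share 6.23 and 7.20. With the letter as a random block these counts were 216 and 271. No clone was called in opposite directions. The horns share the leg arrays in these 2 contrasts, which correlated at 0.72 over clones. With effects removed, the sharing alone gave a simulated mean correlation of 0.44. The covariance was 0.28, against a simulated mean of 0.063 and an average of 0.22 with separate letters.

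Head and thoracic horn differed in 33 clones, 14 with the higher ratio in head horn and 19 with the higher ratio in thoracic horn. OtL016-A04 was higher in head horn by 2.38 ± 0.51 (SE, 5.20-fold, adjusted p = 0.0457 by limma) and OtL009-C06 by 2.33 ± 0.46 (SE, 5.01-fold, adjusted p = 0.0309), each in 5 of 5 letters. Neither was called by limma without letter A, B, D or E, with adjusted p from 0.146 to 0.207 for OtL016-A04 and from 0.0652 to 0.143 for OtL009-C06, nor without the dye term (0.167 and 0.107). With the letter as a random block the adjusted p were 0.00143 and 6.25e-04 (limma), and the same-letter differences ran from 1.84 to 2.66 for OtL016-A04 and from 2.26 to 2.49 for OtL009-C06. OtL014-H10 was 77.2-fold higher in thoracic horn than in head horn (difference -6.27 ± 0.70, SE, adjusted p = 0.00134 by limma). It stood at 3.77 ± 0.50 in thoracic horn, -2.50 ± 0.50 in head horn and -2.51 ± 0.50 in legs, and was called in each. OtP012-E12 was 12.4-fold higher in thoracic horn (difference -3.63 ± 0.49, SE, adjusted p = 0.00346), at 3.62 ± 0.35 there and -0.02 ± 0.35 in head horn. In 4 clones the horns were called with opposite signs against abdomen, and these are named after their values were seen. They were OtL014-H10, OtP012-D08 (negative in head horn) and OtP006-C05 and OtP020-G07 (positive in head horn), and the difference between the horns was called in each. With the letter as a random block, 3 clones had such opposite signs.

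**Figure D2:**
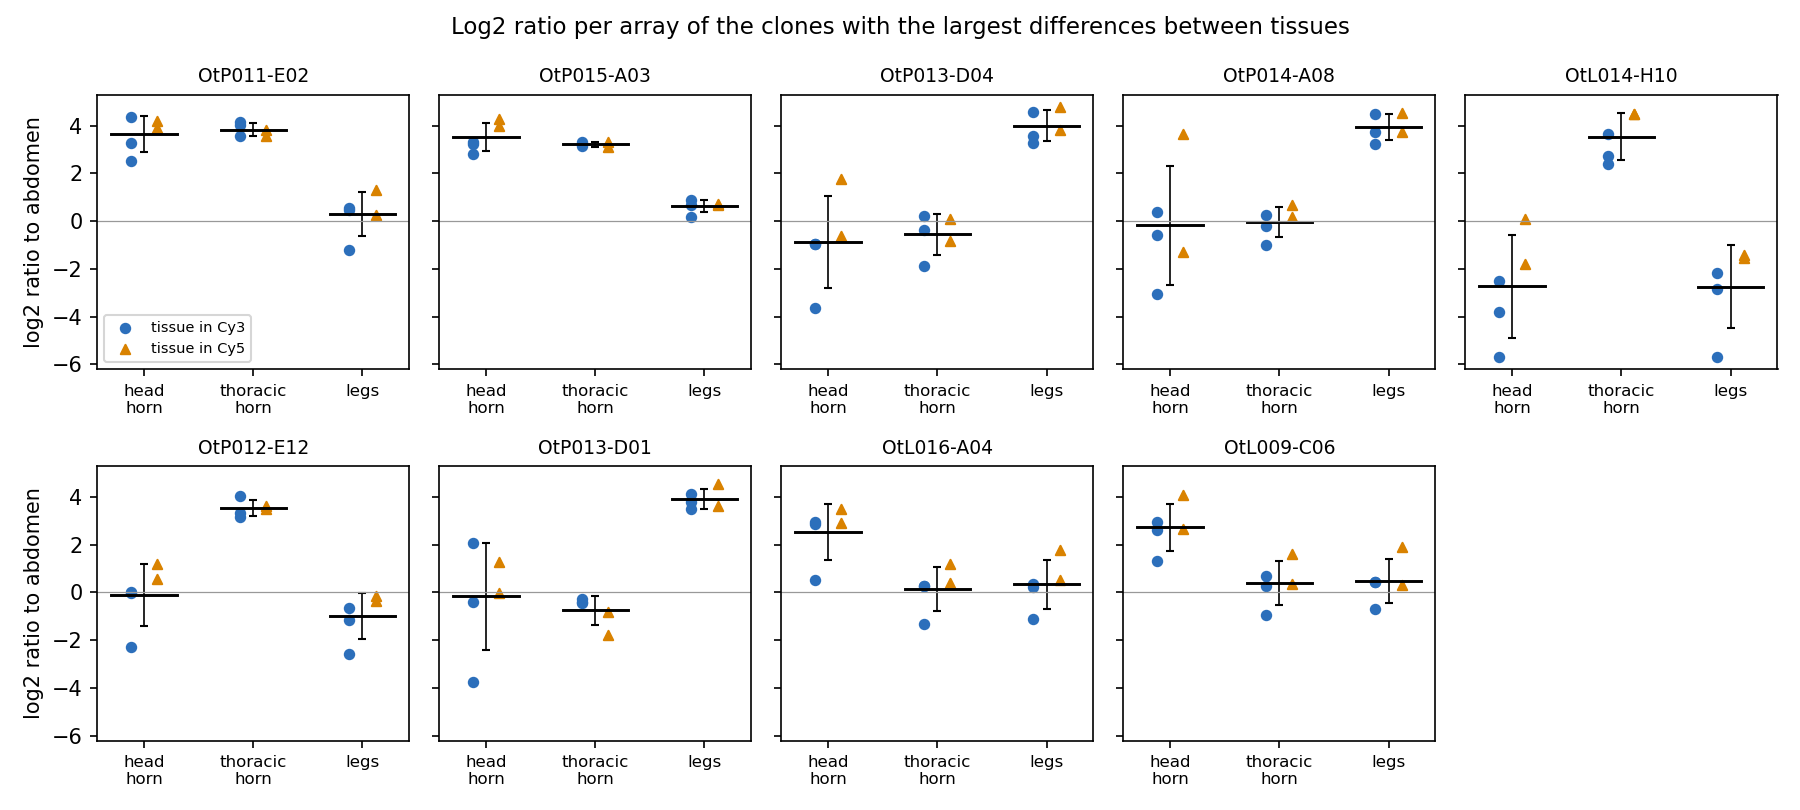
Log2 ratio to abdomen on each array for the 9 clones named in the comparisons between tissues, with circles for arrays with the tissue in Cy3, triangles for Cy5, and black bars for mean and SD (n = 5). OtL014-H10 and OtP012-E12 stand apart in thoracic horn, and OtP013-D04, OtP014-A08 and OtP013-D01 in legs.

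The number of clones called between tissues depended on how letters were handled. Same-letter arrays were paired by their values, and with the letter as a random block the counts were 736 for head horn and legs, 948 for thoracic horn and legs and 101 for the horns. As a fixed block they were 793, 964 and 112. All 244, 415 and 33 clones called without a block were also called in the same direction with the random block. Leaving out any 1 letter lowered the counts to between 72 (without B) and 143 (without A) for head horn and legs, 170 (without C) and 257 (without B) for thoracic horn and legs, and 5 (without D) and 24 (without E) for the horns. Fitted on letters A, C and E alone, 22, 36 and 0 clones were called, and on B and D alone 1, 0 and 0 (limma). At an unadjusted p under 0.05 these fits gave 498, 674 and 190 clones on A, C and E, where 5% of the clones tested is 175.2, and 352, 325 and 158 clones on B and D, where it is 162.6. These fits leave out the pairing of letters, so that share is no exact reference for them.

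The distance between tissues within a letter did not rest on any threshold. Over the 3182 clones with a value on every array, the root mean square difference between head and thoracic horn was 0.62 ± 0.07 (SD, n = 5). It was 0.72 ± 0.06 between head horn and legs and 0.74 ± 0.09 between thoracic horn and legs. The horns were closer to each other than either was to legs in 5 of 5 letters. The two-sided exact sign-flip permutation test gave p = 0.0625 for each of the 2 comparisons, which is the smallest p that 5 letters allow, so the difference could not pass 0.05.

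**Figure D3:**
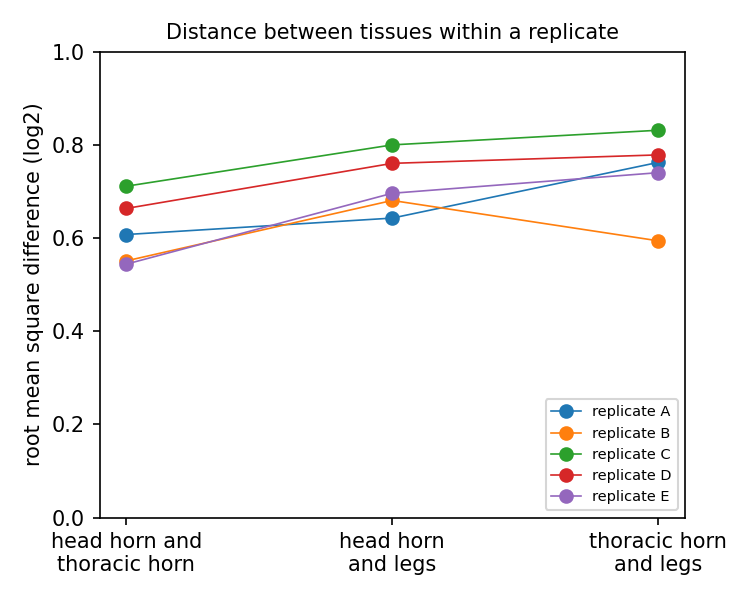
Root mean square difference of log2 ratios between 2 tissues of the same replicate letter, over 3182 clones; each line joins the 3 pairs of 1 letter. The pair of horns has the lowest value in all 5 letters.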

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

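The test of the spread of same-letter differences replaced, after the counts had been seen, a test of standard errors whose outcome the design fixes.

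Replicate D had more empty values than the other arrays in every tissue, with 295 clones in head horn, 321 in thoracic horn and 329 in legs, each beyond Dixon's limit for 5 arrays. Its legs array also had the highest median, 0.15 on the log2 scale. Among single clones, OtP008-D05 stood out on replicate D of thoracic horn at 6.14 and OtL016-A04 on replicate C of head horn at 0.50. These were 6 of 45 such tests, where chance gives about 1 in 20.

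Fewer clones differed between the horns (33) than between head horn and legs (244) or thoracic horn and legs (415). A noisier horn-to-horn contrast is argued against, since same-letter differences between the horns spread 1.02 times as much as those between horns and legs. A single letter does not decide it either, because the horn-to-horn count stayed lowest in 5 of 5 fits that left out a letter. In 100 splits of the 10 arrays of a pair, the real one included, only the real split gave as many clones (1 of 100 in each comparison), and the other splits gave at most 3, 2 and 3 clones; most of these splits break the pairing of letters, and the 16 that keep it are too few for a share under 0.05 (highest other 0, 0 and 1). That the horns are more alike in expression than either is to legs is therefore a hypothesis consistent with these values, and a difference in cell makeup between the tissues stays open, untested.

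The highest and lowest 2 of the clones that differed between each pair of tissues, by the test of the difference itself and the preset rule, were as follows. Between head horn and legs they were OtP011-E02 (3.36), OtP015-A03 (2.89), OtP013-D04 (-4.87) and OtP014-A08 (-4.12). Between thoracic horn and legs they were OtL014-H10 (6.28), OtP012-E12 (4.50), OtP013-D01 (-4.65) and OtP013-D04 (-4.55). Between the horns they were OtL016-A04 (2.38), OtL009-C06 (2.33), OtL014-H10 (-6.27) and OtP012-E12 (-3.63).

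The log ratios also differed between the dye layouts, with 854 clones carrying a called layout term, 499 positive and 355 negative, and a median difference of 0.72 among them. Dye bias of single clones predicts that the real layout gives the highest count, and it did, with 854 against at most 474 for the 9 other choices of 2 letters. A difference in this term between tissues was called by limma in 1, 0 and 0 clones for the 3 pairs (86, 68 and 80 at an unadjusted p under 0.05). The latter are fewer than chance alone gives at that p among the 3777 clones tested, so this test was conservative. An effect of the letters that the tissues share would also give few calls, so these counts do not favour dye bias. A difference between the pupae behind letters B and D and those behind A, C and E cannot be told apart from dye bias. The design puts both on the same letters, and the highest other choice reached only 474. For the comparisons with abdomen, 10 choices of 2 letters as the flipped arrays are too few for a share under 0.05. The real choice gave 1401, 1291 and 1506 clones and the highest other choice 0 in each (1 of 10 choices as large). Any other choice turns the sign of some arrays, so a ratio shared by all arrays largely cancels. The 0 is therefore built into the test and does not bear on chance.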

How the results depend on the processing

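None of the named clones changed sign under any alternative. Their choice by extreme fits and a shared sign made that outcome nearly certain, so it is no test. Of 391 values from fits on more than 1 dye layout, 21 missed the threshold, 11 of them on leaving out a letter. These were values of OtP014-A08 (head horn and legs) and of OtL016-A04 and OtL009-C06 (between the horns); within a dye layout, 5 values missed it on A, C and E (18 did not) and 11 on B and D (12 did not), all of them differences between tissues, among them OtL014-H10 and OtP012-E12 between the horns (adjusted p = 0.252 and 0.324 for both clones) and OtP013-D01 between thoracic horn and legs (0.118 and 0.0609). OtP008-D05 and OtP001-H03 gave no value in some fits that left out arrays or needed every array. With at least 1.5-fold required, 851, 693 and 916 clones were called in head horn, thoracic horn and legs versus abdomen. Separate fits called 721 and 827 clones in head and thoracic horn versus abdomen, 66 in head horn versus legs and 7 between the horns, with fewer degrees of freedom. Letters A, C and E alone gave 889, 709 and 994 clones against abdomen and 22, 36 and 0 between tissues. Letters B and D alone gave 797, 500 and 741, then 1, 0 and 0. Both fits were chosen after seeing the data, rest on fewer arrays and hold no layout term, so dye bias can enter counts against abdomen. Between tissues, in the order head horn and legs, thoracic horn and legs, and the horns, dropping the dye term gave 104, 216 and 19, and a dye term per tissue (chosen after seeing the data) 98, 189 and 16. The replicate block gave 736, 948 and 101 as a random term and 793, 964 and 112 as a fixed one. With the random block, clones with both horns above or below legs went from 71 and 86 to 216 and 271, while counts against abdomen stayed within 1.5 times. Scaling arrays to one spread gave 21 between the horns. Leaving out 1 letter gave 72 to 143, 170 to 257 and 5 to 24. The cause was not tested where none is given. Counts against abdomen when leaving out a letter (lowest without D, 1123, 1004 and 1194), overlaps between the lists against abdomen, and other alternatives for these counts stayed within 1.5 times. Turning every sign gave 713, 654 and 665 positive calls against abdomen. The alternatives planned for gene lists (estimated correlation, fry, no dye term, means per gene, leaving out letters) were not run, as clones have no gene names. Signal over background could not be examined here.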

Other observations

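The groups of clones in this part, and the tests of plates, of bins of spread and of its spline, were chosen after seeing the data. A group of 14 clones was at least 4-fold positive in legs and below legs in ratio in both horns. Their median fitted ratio was 3.29 in legs, 0.10 in head horn and 0.34 in thoracic horn. None of the 14 was called against abdomen in head horn and 3 were called in thoracic horn. They came from 10 plates, 12 with the prefix OtP and 2 with OtL, and included OtP013-D04, OtP013-D01 and OtP014-A08. A further 6 clones were at least 4-fold positive in both horns and above legs in both, with medians of 3.54 in head horn, 3.06 in thoracic horn and 0.69 in legs. OtP011-E02, OtP015-A03, OtL002-E05 and OtP020-E08 were among them.

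A group of 44 clones was at least 4-fold negative in legs and higher in thoracic horn than in legs. Its median was -2.64 in legs, -1.89 in head horn and -0.86 in thoracic horn, and 32 of the 44 had the prefix OtL. Of these clones, 43 were called negative in head horn and 28 in thoracic horn, and 9 were called higher in thoracic horn than in head horn. Clones that went opposite ways in horns and legs were few. Head horn and legs were called against abdomen with opposite signs in 17 clones, and thoracic horn and legs in 28. Of the 28, 11 were positive in thoracic horn, a class of 8 with the letter as a random block. In 3 clones both horns were called positive and legs negative with both differences called (OtL005-F04, OtL009-G05 and OtP003-H01), and 4 clones did the reverse (OtL003-A04, OtP003-H08, OtP004-A10 and OtP014-G05). Among them OtL009-G05 stood at 0.67 ± 0.11 in head horn, 0.61 ± 0.11 in thoracic horn and -0.86 ± 0.11 (SE) in legs.

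In 349 clones with a value on every array, the fitted ratio was at least 1.5 (log2) in absolute size, positive or negative, in some tissue. Of these, 184 fell into groups of similar profile by average linkage at a correlation of 0.9. The 4 largest groups had 14, 11, 11 and 9 clones, all positive in the 3 tissues by their medians. In the same order, 13, 9, 4 and 9 of these clones had the prefix OtL. The group of 14 had medians of 2.71 in head horn, 1.86 in thoracic horn and 1.51 in legs.

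Against abdomen, OtL clones were called more often than OtP clones. In at least 1 tissue 63.6% of OtL and 52.2% of OtP clones were called, an odds ratio of 1.60 (95% interval 1.41 to 1.83). This interval, those below and the Fisher tests take clones as independent. Several clones can come from 1 transcript, so the intervals may be too narrow. Between tissues the difference did not pass the test for thoracic horn and legs (11.8% against 10.1%, adjusted p = 0.107 by two-sided Fisher's exact test over clones) or the horns (1.16% against 0.584%, adjusted p = 0.0947), and it did for head horn and legs (7.71% against 5.20%, adjusted p = 0.00275). A few plates do not account for it, since the two-sided permutation of the plates between prefixes gave p = 1e-05, the smallest that 100000 permutations can give. Empty values in OtP clones as the whole cause are argued against, because clones with a value on every array still differed by 7.87 percentage points (4.49 to 11.3). OtP clones spread more between arrays, with a median residual SD 1.27 times that of OtL clones (1.21 to 1.35), which goes with fewer calls. Spread as the whole cause is argued against by an odds ratio of 1.39 (1.21 to 1.60) within 20 bins of equal clone number by residual SD, and of 1.39 (1.21 to 1.60) in a logistic model with a spline of the log residual SD, so spread may account for part only, and signal strength and the origin of the clones, which the labels do not give, stay open and no biological explanation was tested.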
